A study of Homo sapiens with 6 samples.

How the data were processed

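The series holds 6 samples from cultured human coronary artery smooth muscle cells: 1 input DNA, 2 SRF ChIP-seq, 1 ATAC-seq, 1 H3K27ac ChIP-seq and 1 TCF21 ChIP-seq library. Per the labels, DNA from 2 biological replicates was combined for each SRF library, and the ATAC, H3K27ac and TCF21 samples were re-analysed from earlier series. The growth and extraction text of the re-analysed samples repeats that of the SRF samples, so conditions of the earlier cultures were taken as unknown. The submitters' processing notes name FastQC, cutadapt, BWA, Picard, SAMtools and MACS2 and the build hg19, with no versions. The order of the steps, read filters, peak thresholds, use of the input as control and any shift of ATAC reads to the transposase cut site are not given in the sources used here. An unshifted ATAC signal would move peak edges by a few bases, and the treatment of reads that map to several places decides which repeats carry peaks.

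Samples were grouped by assay from the labels. The deposited files were 4 peak lists without headers, 1 per assay, and each was treated as 1 list for its assay because none separates replicates. Whether the SRF list was called on 1 SRF library or on both is not given in the sources used here. In the SRF and TCF21 lists, which have 5 columns, the score of each peak is the value deposited by the authors; its scale is not stated, it starts at 50, and 8 SRF and 43 TCF21 peaks tie at 3100. The layout, peak names and lowest score of these 2 lists resemble output of a MACS version before MACS2, whose score is 10 times the −log10 of p, while the submitters' processing notes name MACS2; this was not settled, so a difference of scores has no stated unit. In the ATAC and H3K27ac lists, which have 9 columns, the authors deposited a score, a fold enrichment (a linear ratio over the caller's background) and the −log10 of a p-value and of a q-value for each peak. The score equalled the whole part of 10 times the −log10 q in all but 7 ATAC and 3 H3K27ac peaks, and the highest q was 0.0996 in the ATAC list and 0.0989 in the H3K27ac list. The unlike formats point to unlike calling settings, so scores were used only within their own list, to rank or split its peaks and to compare median scores between them. No list gives summits, and midpoints of peaks were used in their place. The lists give no read counts, so depth is unknown, and the binomial intervals cover the number of peaks only.

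Peak numbers in the names of the ATAC list skip 797 values, while those of the H3K27ac list skip none. The reason is not given in the sources used here. Any skip before the first peak or at a change of chromosome counts among the 797 but was not placed. The skips between peaks of the same chromosome fall in 112 intervals that span 157 Mb. These intervals hold 47 SRF peaks and 1512 TCF21 peaks, which could not overlap an ATAC peak. Peaks on unplaced contigs and alternate haplotypes, 48 of the SRF list and 401 of the TCF21 list, were kept in all main results and left out in alternatives.

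Overlap meant at least 1 bp shared. Each share has an exact (Clopper-Pearson) 95% interval and was set against 1000 random placements of the first list within its own chromosomes, between the first and last peak of any list; the two-sided p cannot fall below 0.002. The chance means of the 10 groups by score came from fewer than 1000 placements. Placement ignores gaps, mappability and gene density. Co-location was tested with Fisher's exact test (two-sided, Wald interval of the odds ratio) on the ATAC peaks, which did not overlap each other. Odds ratios within bins are Mantel-Haenszel estimates over 10 bins of ATAC score, or over 10 bins of score by 10 of width. Differences of medians were tested by two-sided permutation with 100000 resamples, and the 3 tests of H3K27ac were adjusted by the Benjamini-Hochberg method. A threshold of 0.05 was used. Peaks are not replicates, neighbouring peaks are not independent, and p-values describe these lists only.

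Groups, tests and most alternatives were fixed before the data were examined. Alternatives covered stricter scores, overlap of at least 50% of the shorter peak, midpoints within 100 bp (for H3K27ac, whose peaks are broad, the midpoint inside an H3K27ac peak), autosomes, other sets of regions, equal list lengths and width in place of score. The bins of score and width, and the comparisons of groups by score and of single chromosomes, were chosen after seeing the data. Named regions followed a rule fixed in advance: the 10 highest-scoring SRF peaks, the 10 highest-scoring TCF21 peaks and the 10 highest-scoring SRF peaks that overlap TCF21, with ties taken by position. The rule also named genes near peaks and 16 gene lists, which need an hg19 annotation. The gene table at hand is of another build, so gene names, promoter position, gene lists and sequence motifs were not analysed here.

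Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. All 24 overlap counts checked against bedtools 2.31.1 were equal. In simulated data on the 71784 ATAC peaks, the presence of each factor depended on ATAC score and not on width. With no association beyond score, the crude odds ratio averaged 1.27 and that within bins of score and width 1.01. With a true odds ratio of 2 the averages were 2.50 and 2.00. In each case 19 of 20 intervals within bins held the true value. The simulation therefore could not show whether the bins remove an effect of width. Of 100 randomly placed lists of 2779 peaks, 6 had a placement p under 0.05 against TCF21; a first run with 20 lists had been extended to 100. The permutation test gave p = 0.76 for 3000 simulated values with no difference and 1e-05, the smallest possible, for a 1.4-fold difference.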

Results

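The series describes where serum response factor (SRF) and TCF21 bind in cultured human coronary artery smooth muscle cells (HCASMC). SRF is a DNA-binding factor that, with its partner myocardin, drives genes of the contractile smooth muscle program. TCF21 is a basic helix-loop-helix factor associated with coronary disease. The series title describes TCF21 as a block on the myocardin and SRF pathway, so the question the lists can address is where the 2 factors occupy the same regions. For SRF, the cells were primary HCASMC from a commercial source, grown with serum; the culture conditions behind the re-analysed samples were taken as unknown. The 6 samples comprised 2 SRF chromatin immunoprecipitation (ChIP-seq) libraries and 1 library each of input DNA, ATAC-seq, H3K27ac ChIP-seq and TCF21 ChIP-seq. ATAC-seq maps open chromatin, and acetylation of histone H3 at lysine 27 (H3K27ac) marks active promoters and enhancers. The labels mark the ATAC, H3K27ac and TCF21 samples as re-analysed from earlier series.

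The data used were 4 peak lists, 1 for each assay. The labels attach 1 SRF list to both SRF libraries, and whether it was called on 1 of them or on both is not given in the sources used here. No list of the input DNA was used. The SRF list was the smallest, with 2779 peaks that covered 1.01 Mb, a median width of 327 bp and scores from 50.02 to 3172.98. The TCF21 list held 42920 peaks over 14.9 Mb, with a median width of 325 bp and scores from 50 to 3230.05. ATAC peaks numbered 71784, covered 47.7 Mb and had a median fold enrichment of 4.02. H3K27ac peaks numbered 64293, covered 136 Mb and had a median fold enrichment of 3.33. No read counts were used, so the depth behind each list was unknown, and the difference in length between the SRF and TCF21 lists is not a measured difference in binding. No list separated replicates, so intervals and p-values below describe these lists and not the spread between cultures.

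SRF peaks lay mostly in open or acetylated chromatin. Of the 2779 SRF peaks, 1673 overlapped an H3K27ac peak (60.2%, 95% interval 58.4 to 62.0) and 1505 overlapped an ATAC peak (54.2%, 52.3 to 56.0). Random placement of the SRF peaks within their chromosomes gave means of 5.50% and 2.63%, so the observed shares were 10.9 and 20.6 times those of chance. The overlaps divided the list into 1291 peaks with both an ATAC and an H3K27ac peak (46.5%), 214 with ATAC alone (7.70%), 382 with H3K27ac alone (13.7%) and 892 with neither (32.1%, 30.4 to 33.9). The median score was 140 in the first of these classes and 66.0 in the last. Both overlap tests gave a two-sided p of 0.002, the smallest that 1000 placements can give. The share with an ATAC peak was 16.8% when midpoints had to lie within 100 bp of each other, against 0.499% by chance.

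TCF21 peaks also lay far more often in open or acetylated chromatin than chance placed them. H3K27ac peaks overlapped 21972 of the 42920 TCF21 peaks (51.2%, 50.7 to 51.7), and ATAC peaks overlapped 19544 (45.5%, 45.1 to 46.0). The chance means were 5.46% and 2.69%. A total of 15032 TCF21 peaks had both overlaps (35.0%), 4512 had ATAC alone, 6940 had H3K27ac alone, and 16436 had neither (38.3%, 37.8 to 38.8). The p of the placements was again 0.002, the smallest possible. With midpoints within 100 bp the share with an ATAC peak was 14.8%, against 0.498% by chance. The 2 lists differ in length and source, and the difference between their shares was not tested.

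**Figure D1:**
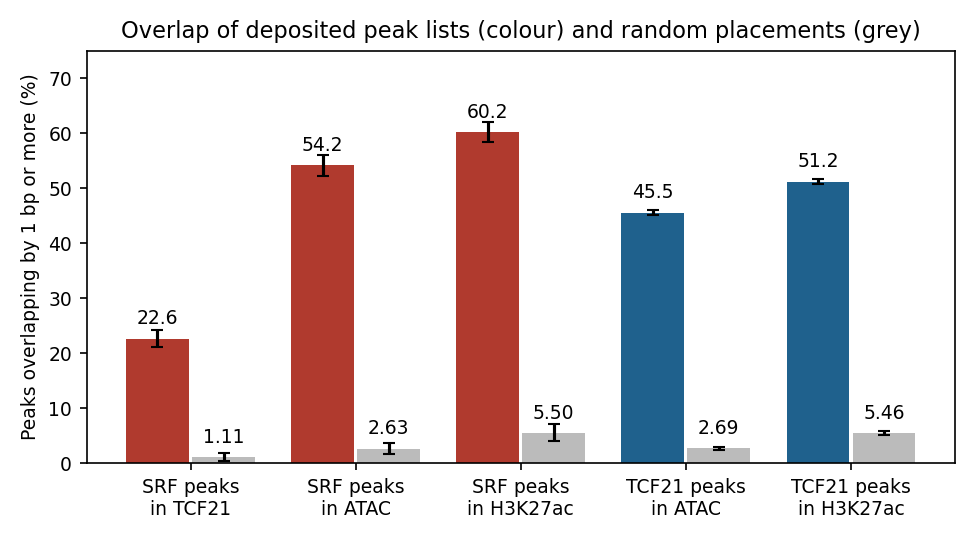
Percentage of SRF peaks (red) and TCF21 peaks (blue) that overlapped a peak of another list by at least 1 bp, with exact 95% binomial intervals. Grey bars give the mean of 1000 random placements with their full range as bars; every observed share, from 22.6% to 60.2%, lay above that range.

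SRF and TCF21 peaks coincided far more often than random placement gave. TCF21 peaks overlapped 629 of the 2779 SRF peaks (22.6%, 21.1 to 24.2), against a chance mean of 1.11% and a range of 0.468% to 1.80% over the placements, a ratio of 20.4. Seen from the longer list, 641 of the 42920 TCF21 peaks overlapped an SRF peak (1.49%, 1.38 to 1.61), against 0.0722% by chance. TCF21 was found at 32.9% of the SRF peaks that had both ATAC and H3K27ac overlaps, at 24.3% of those with ATAC alone, at 16.8% of those with H3K27ac alone and at 9.87% of those with neither. A TCF21 midpoint lay within 100 bp of the SRF midpoint for 319 SRF peaks (11.5%), against 0.306% by chance. It lay within 1000 bp for 815 (29.3%) and within 10000 bp for 1563 (56.2%). The median distance to the nearest TCF21 midpoint was 6555 bp. No chance value was computed for the wider distances or for the median, so these do not show an excess. The placements gave a two-sided p of 0.002 in both directions, the smallest possible. The shared fraction was lower under stricter cuts, which left fewer TCF21 peaks to overlap and lowered the chance share as well. With only the 2779 highest-scoring TCF21 peaks it was 2.30%, against 0.101% by chance. Between the highest-scoring 25% of each list it was 11.2%, against 0.490%.

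Random placement does not account for the tendency of both factors to sit in open chromatin, so co-location was measured again among the 71784 ATAC peaks. SRF occupied 1480 of these open regions and TCF21 occupied 18118. Both occupied 617, SRF alone 863, TCF21 alone 17501 and neither 52803. TCF21 was present in 41.7% of SRF regions (39.2 to 44.2) and in 24.9% of the other open regions (24.6 to 25.2), and independence of the 2 factors would have put both in 374 regions. The odds ratio was 2.16 (95% interval 1.94 to 2.40, Fisher's exact test, two-sided p = 3.4e-44). Stronger and wider ATAC peaks carried either factor more often. Within bins of ATAC score and width the odds ratio was 1.45 (1.30 to 1.61), and within such bins among regions with H3K27ac it was 1.27 (1.13 to 1.43); both settings were chosen after seeing the data.

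**Figure D2:**
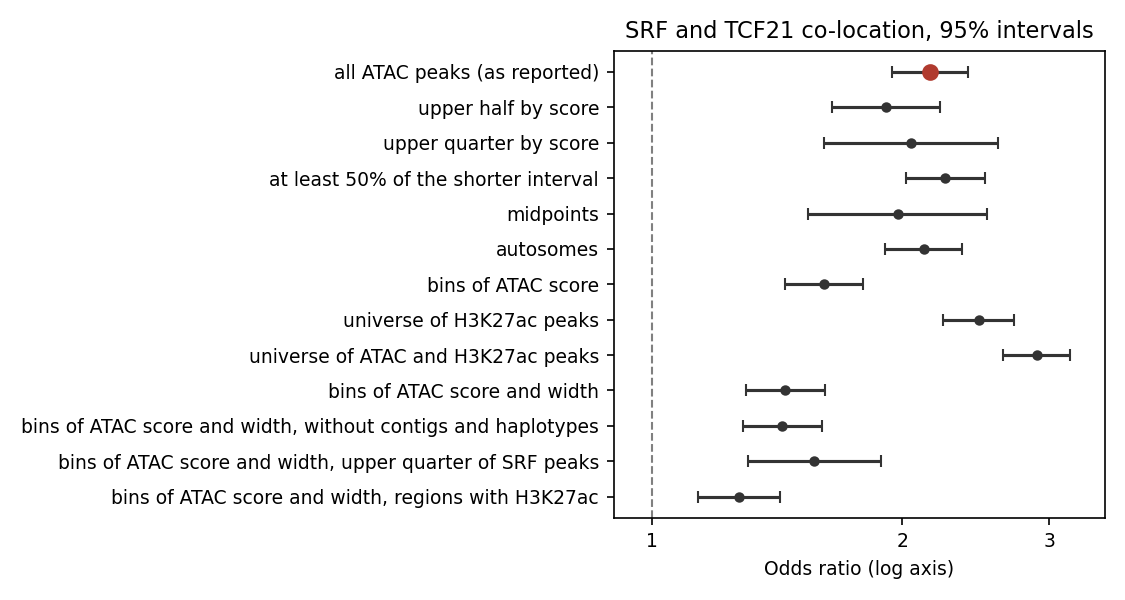
Odds ratio of SRF and TCF21 in the same region, on a log axis, with 95% intervals, for all ATAC peaks (red) and for each other setting (black), which include regions defined by H3K27ac peaks. The dashed line marks an odds ratio of 1; the estimates ran from 1.27 to 2.90 and no interval reached the line.

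Acetylation was most frequent where both factors were present. H3K27ac overlapped 561 of the 617 shared open regions (90.9%, 88.4 to 93.1), 731 of the 863 with SRF alone (84.7%, 82.1 to 87.0), 13745 of the 17501 with TCF21 alone (78.5%, 77.9 to 79.1) and 27873 of the 52803 with neither factor (52.8%, 52.4 to 53.2). Shared regions exceeded TCF21-only regions with an odds ratio of 2.74 (2.08 to 3.61, Benjamini-Hochberg adjusted p = 2.0e-15 over 3 Fisher's exact tests). In the same exact tests, SRF-only regions exceeded TCF21-only regions with an odds ratio of 1.51 (1.25 to 1.83, adjusted p = 1.3e-05), and shared regions exceeded SRF-only regions with an odds ratio of 1.81 (1.30 to 2.52, adjusted p = 0.00036). The classes also differed in the ATAC peak itself: the median ATAC score was 67 in shared regions, 51 with SRF alone, 47 with TCF21 alone and 31 with neither, and median widths were 937, 712, 671 and 492 bp. Within bins of ATAC score and width, a setting chosen after seeing the data, the excess of shared over SRF-only regions was no longer detectable (odds ratio 1.12, 0.766 to 1.63), and that over TCF21-only regions was 1.62 (1.22 to 2.17).

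SRF peaks that coincided with TCF21 had higher SRF scores. Their median was 128 in 629 peaks, against 94.5 in the 2150 SRF peaks without TCF21, a difference of 34.0 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The difference was not found among the SRF peaks that lay in open chromatin: there the medians were 132 in 477 peaks with TCF21 and 130 in 1028 without, a difference of 2.01 (permutation p = 0.74). With the SRF midpoint required to lie inside a TCF21 peak, over all SRF peaks, the difference was 25.9 (permutation p = 3e-05). TCF21 peaks that coincided with SRF also scored higher, with a median of 180 in 641 peaks against 140 in 42279 others, a difference of 40.1 (permutation p = 1e-05, again the smallest possible). This difference was 28.3 among TCF21 peaks in open chromatin (permutation p = 0.025) and 19.6 when the TCF21 midpoint had to lie inside an SRF peak (permutation p = 0.032). Both midpoint settings were chosen after seeing the data. Score and width moved together, with a Spearman correlation of 0.84 across SRF peaks and 0.88 across TCF21 peaks, which are not independent replicates, and wider peaks overlap more by geometry alone.

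Peaks of higher score lay more often in open, acetylated chromatin. From the lowest-scoring 10% of SRF peaks to the highest-scoring 10%, overlap with ATAC went from 30.9% (25.6 to 36.7) to 76.3% (70.8 to 81.1), overlap with H3K27ac from 32.4% to 83.8%, and overlap with TCF21 from 12.9% (9.24 to 17.5) to 32.7% (27.2 to 38.6). For TCF21 peaks the same ends gave 32.0% and 62.8% for ATAC, 35.3% and 68.8% for H3K27ac, and 0.932% and 1.93% for SRF. Random placement of these wider peaks also gave more overlap, from 2.43% to 3.20% for SRF in ATAC, from 0.923% to 1.50% for SRF in TCF21 and from 0.0552% to 0.0970% for TCF21 in SRF. The highest 10% exceeded the lowest in Fisher's exact tests of all 6 pairs of lists, with odds ratios from 2.10 for TCF21 in SRF (adjusted p = 0.00014) to 10.8 for SRF in H3K27ac (adjusted p = 9.8e-36). With midpoints required to lie inside the other peak, so that the width of the first list plays no part, the exact tests gave odds ratios for these 2 pairs of 1.82 (adjusted p = 0.0077) and 8.29, and that for SRF in TCF21 went from 3.27 to 2.43 (adjusted p = 0.00021). All 12 tests were adjusted together and were chosen after seeing the data.

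**Figure D3:**
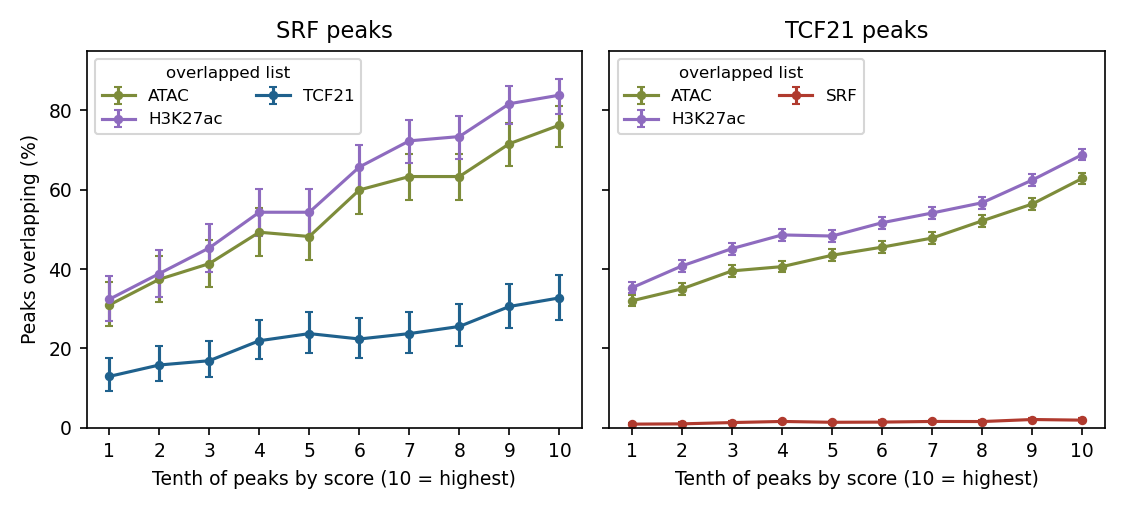
Percentage of SRF peaks (left) and TCF21 peaks (right) that overlapped each other list, in 10 groups of equal size in order of score, with exact 95% binomial intervals. SRF overlap with ATAC went from 30.9% to 76.3% and TCF21 overlap with ATAC from 32.0% to 62.8%.

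Most of the strongest SRF regions were open and acetylated. Among the 10 highest-scoring SRF peaks, 10 overlapped H3K27ac, 9 overlapped ATAC and 7 overlapped TCF21; among the highest 100 the numbers were 90, 80 and 39, and 77 overlapped both H3K27ac and ATAC (67.5% to 84.8%). Positions are 1-based in build hg19. The highest score, 3172.98, belonged to chromosome 16, 66545411 to 66546232, which overlapped a TCF21 peak of score 120.01 and a 6397 bp H3K27ac peak of 4.25-fold enrichment but no ATAC peak. A group of 8 SRF peaks shared the score of 3100, and 5 of these overlapped TCF21. On chromosome 8, 42270125 to 42270839, an SRF peak of score 3100 overlapped a TCF21 peak of score 547.87, an ATAC peak of 5.50-fold and an H3K27ac peak of 4.58-fold enrichment. On chromosome 5, 137800384 to 137801285, the TCF21 peak scored 175.39, the ATAC peak had a fold enrichment of 4.33 and the H3K27ac peak one of 5.01. The peak on chromosome 10, 64575894 to 64576896, met TCF21 only at its edge, over 30 bp, with a TCF21 score of 51.55. The peak on chromosome 17, 43394299 to 43395158, overlapped a TCF21 peak of score 75.73. On chromosome 19, 40926522 to 40927279, the SRF score was 3074.71 and the TCF21 score 385.88.

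The strongest SRF regions without a TCF21 peak were chromosome 1, 39492100 to 39492832, chromosome 21, 34752761 to 34753591, and chromosome 5, 60627680 to 60628193, all with a score of 3100. Each overlapped an ATAC peak, of 5.69-fold, 5.41-fold and 2.73-fold enrichment in that order, and an H3K27ac peak, of 5.80-fold, 3.58-fold and 4.70-fold. The next shared peaks in order of SRF score were chromosome 12, 109085182 to 109085848, with an SRF score of 2698.43 and a TCF21 score of 175.88, chromosome 1, 202474413 to 202475110, with scores of 2592.76 and 57.17, and chromosome 10, 112257326 to 112257775, with scores of 2483.43 and 121.66. The last 2 met TCF21 only at their edges, over 30 bp and 3 bp. The remaining peak at 3100 lay on an alternate haplotype sequence of chromosome 17, at 9435 to 10294. It had the same width as the chromosome 17 peak, 860 bp, and whether both come from the same reads was not tested.

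**Figure D4:**
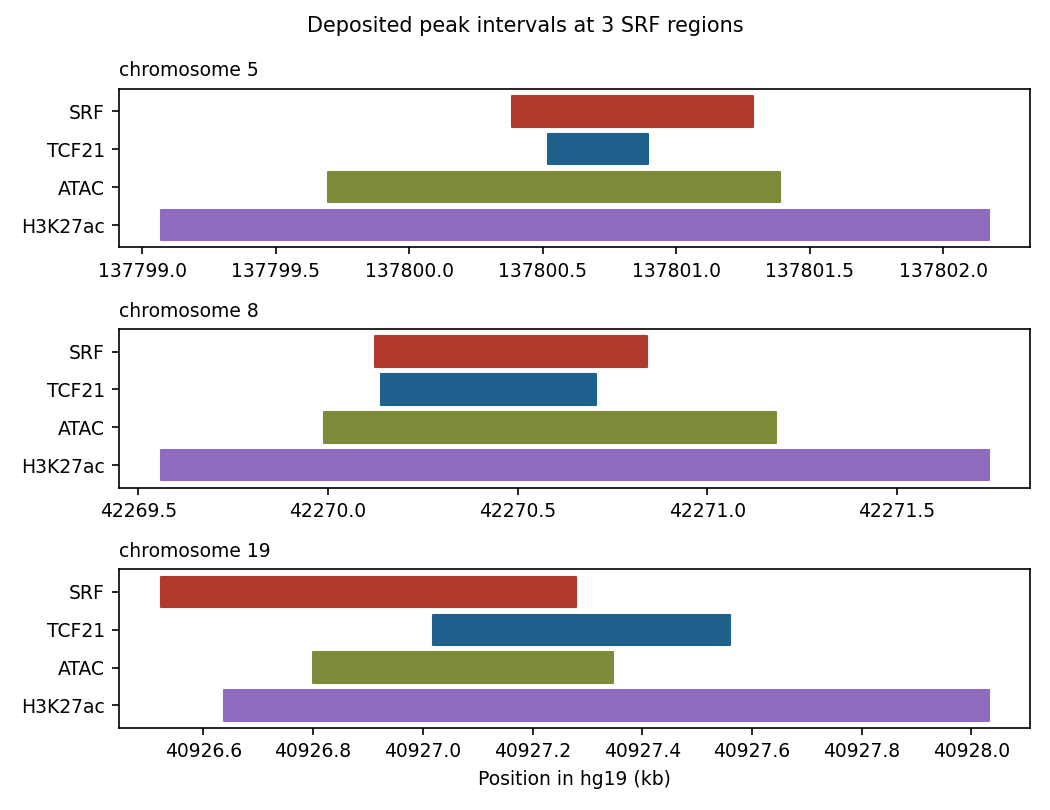
Deposited peak intervals at 3 of the 10 highest-scoring SRF regions, on chromosomes 5, 8 and 19, with position in hg19 in kb on the horizontal axis and 1 line per list. The SRF and TCF21 intervals overlapped in each region. The TCF21 interval lay within the SRF interval on chromosome 8, at 42270139 to 42270705, and on chromosome 5, at 137800519 to 137800894.

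Few of the strongest TCF21 regions carried SRF. None of the 10 highest-scoring TCF21 peaks and 2 of the highest 100 overlapped an SRF peak (2%, 0.243 to 7.04), while 76 of the 100 overlapped ATAC and 77 overlapped H3K27ac. The highest score, 3230.05, was on chromosome 8, 124604549 to 124605224, in an ATAC peak of 3.34-fold and an H3K27ac peak of 5.35-fold enrichment. It was followed by chromosome 4, 140449658 to 140450289, which overlapped an ATAC peak of 5.59-fold enrichment and no H3K27ac peak, and by chromosome 5, 112630367 to 112630939, with an ATAC peak of 4.27-fold and an H3K27ac peak of 5.41-fold enrichment. The peaks on chromosome 18, 59684998 to 59685823, chromosome 22, 36835689 to 36836412, chromosome 1, 151254037 to 151254825, chromosome 8, 118725457 to 118726258, and chromosome 3, 49977057 to 49978149, also overlapped both lists. The peaks on chromosome 1, 111177040 to 111177821, with a score of 3197.21, and chromosome 5, 176521224 to 176522037, with a score of 3178.97, overlapped neither. The highest 100 are too few to set against the 1.49% of the whole list; in the highest-scoring 10% of TCF21 peaks, SRF was at 83 of 4292 (1.93%, 1.54 to 2.39).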

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

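Of 55 alternatives to the reported results, 53 kept the direction and the side of the threshold, 2 kept the direction but no longer passed, and none turned around. The bins of ATAC score and width and the midpoint rule for scores were chosen after seeing the data. The rest were planned. The tally says little about the shares, since each of their alternatives was only set against random placement and gave the smallest possible p. The log10 of the score keeps the order of the peaks, so that alternative could hardly change the direction. The difference in SRF score with and without TCF21 was 2.01 among SRF peaks in ATAC peaks (permutation p = 0.74), and the odds ratio of H3K27ac in shared against SRF-only regions was 1.12 within the bins; the cause was not tested. The co-location odds ratio ran from 1.27 to 2.90 over 12 alternatives. The share of SRF peaks with TCF21 ran from 2.30% to 23.0%, with ATAC from 16.8% to 71.9% and with H3K27ac from 56.3% to 81.3%. The share of TCF21 peaks with ATAC ran from 14.8% to 58.3% and with H3K27ac from 47.8% to 64.0%, always above chance. The midpoint alternative asked for midpoints within 100 bp for ATAC but only for a midpoint inside the peak for H3K27ac, so the ranges of these lists are not comparable. The odds ratios of H3K27ac ran from 1.62 to 2.81 for shared against TCF21-only regions and from 1.43 to 1.66 for SRF-only against TCF21-only regions. Leaving out a replicate was not possible because no list separates replicates. Alternatives for promoters, genes, gene lists and motifs were not run, since no hg19 genome or annotation was used. Depth is unknown, so a region without a peak is not shown to be unbound.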

Other observations

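The tests of chromosomes, of score groups, of skipped intervals, of contigs and within bins of ATAC score and width in this part were chosen after the overlap results were seen. SRF and TCF21 were spread unevenly over the autosomes. SRF was in 4.55% of the ATAC peaks of chromosome 19 (3.56 to 5.71), the highest share of the 22 autosomes, against 2.02% on the others, an odds ratio of 2.31 (1.81 to 2.95, Fisher's exact test, adjusted p over 22 autosomes = 4.3e-08) and 2.20 (1.72 to 2.82) within bins of ATAC score and width. TCF21 was in 30.3% of the ATAC peaks of chromosome 19 against 25.4% elsewhere, an odds ratio of 1.28 (1.14 to 1.43) and 1.22 (1.09 to 1.37) within bins, but its share was higher on chromosomes 22 (34.7%), 17 (32.9%) and 15 (30.4%). Chromosome 4 had the lowest share of both, 1.20% for SRF and 20.5% for TCF21. After adjustment, 3 autosomes were higher and 1 lower than the rest for SRF, and 7 were higher and 5 lower for TCF21. Chromosome 19 was picked because its SRF value was extreme, and gene density was not analysed here.

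In open regions with 1 SRF and 1 TCF21 midpoint each, the midpoints lay close together. The median distance in 500 such regions was 146 bp (interquartile range 70 to 319), and 181 regions (36.2%, 32.0 to 40.6) had both within 100 bp.

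The first pattern weighed is the presence of SRF and TCF21 in the same open regions. Binning by strength and width of the region lowered the association but did not remove it. The odds ratio was 2.16 over all open regions and 1.45 (1.30 to 1.61) within bins of both. Within such bins among regions with H3K27ac it was 1.27 (1.13 to 1.43). The simulation could not show whether the bins remove an effect of width, so what strength and width account for was not decided. Unplaced contigs and alternate haplotypes held 11 of the 617 shared regions. Without them the odds ratio within bins was 1.43 (1.29 to 1.60), so they were not the whole cause of the association within bins. Weak SRF calls were not either, with an odds ratio within bins of 1.57 (1.30 to 1.88) for the highest-scoring 25% of SRF peaks. The median distance of 146 bp was shorter than in every one of 100000 permutations of the offsets among regions of like width (mean 214 bp, range 170 to 264, one-sided p = 1e-05, the smallest possible), which is consistent with a common site within the region. A most accessible point inside each region could give the same distance without any relation between the factors, and repeats within chromosomes, promoter position, residual differences within bins and signal common to all ChIP libraries also stay open, so no biological explanation was established.

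The second pattern is the 892 SRF peaks outside both the ATAC and the H3K27ac list. Weak calls may account for part of them, since the share outside was 55.5% (51.8 to 59.3) in the lowest-scoring 25% of SRF peaks, but 13.4% (10.9 to 16.1) of the highest-scoring 25% also lay outside, so weak calls were not the whole cause. The intervals within chromosomes where ATAC peak names skip numbers held 46 of the 892 (5.16%, 3.80 to 6.82), a small part. Contigs or haplotypes held 19. The highest-scoring autosomal ones, picked after their values were seen, were chromosome 11, 76758448 to 76759110, with a score of 1780.12 and no TCF21 peak, and chromosome 1, 203259462 to 203260157, with a score of 1587.51 and a TCF21 peak of 337.51; 2 of the 10 highest and 88 of all 892 (9.87%) overlapped TCF21. Different cultures behind the lists and the thresholds of the ATAC and H3K27ac lists stay open, and no biological explanation was tested.

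The third pattern is the higher frequency of H3K27ac in SRF-only than in TCF21-only open regions, 84.7% against 78.5%. The difference remained within bins of strength and width of the ATAC peak. The odds ratio within bins of both was 1.46 (1.20 to 1.79). Differences in strength and width inside a bin stay open, and the simulation could not show whether the bins remove an effect of width. The lengths of the lists stay open as a technical source, since the SRF list is far shorter and may hold only the firmer sites, and so does promoter position, which was not analysed here. No biological explanation was tested.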
